A study of Mus musculus with 10 samples.

How the data were processed

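The samples were grouped by their titles into 5 control and 5 prenatal testosterone testes. The authors scanned each array and extracted spots with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. Per the file headers, the processed signal is a spot intensity on a linear scale, after background subtraction, spatial detrending and a linear plus lowess dye normalization, so the ratio of the channels has a median close to 0 on each array by construction. Median spot and background intensity, also deposited, are pixel brightness with no correction. Other deposited columns are flags of 0 or 1 that mark spots well above background, saturated or outlying. Per the labels, spike-in RNA was added in equal amount to the IP and Sup fractions, which were amplified and labelled separately, Sup with Cy3 and IP with Cy5. No dyes were swapped, so dye and fraction cannot be separated.

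The authors' value table is on a log2 scale. Set against the scanner files, each of its 44264 rows is the log2 Cy5 processed signal minus 1 constant per array, so its channel is known and the origin of the constants is not. Its column medians were 1.47, 2.19, 2.22, 1.89 and 2.25 for control replicates 1 to 5 and 2.03, 1.88, 1.26, 1.98 and 1.38 for testosterone replicates 1 to 5. It holds no Sup channel and served only as an alternative for abundance.

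Each array held 62976 spots, of which 61537 were not control spots. Spots marked as outliers in either channel (330 to 682 per array) and control spots were left out, and spots of a probe were averaged on the log2 scale. No spot used was saturated. The IP/Sup ratio was log2 of the Cy5 over the Cy3 processed signal minus the array median. No further loess was run, since many transcripts can lie on either side. The lowess dye normalization of the processed signal was already in these values. RNA abundance was log2 of the sum of both channels, each divided by its 75th percentile on that array. Both fractions therefore count alike, whatever amount of RNA each held. Probes were tested for the ratio if well above background in both channels on at least 5 of the 10 arrays, and for abundance if well above background in at least 1 channel on at least 5 arrays. From each, 8 probes with no unflagged value in a group were left out because no difference can be fitted, a step added after the data were examined. Spike-in probes were identified by their probe names only: 102 probes, of which 22 were well above background in both channels on all 10 arrays.

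Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The IP side and the Sup side were called from the mean of the group means against 0, with at least a 2-fold ratio. The overall level was compared by an exact two-sided permutation test over 252 arrangements. The functions were tested on simulated data drawn from the real probes' means and spreads. Of 39337 probes simulated for the ratio, 45 of 100 changed 2-fold and 2 of 100 changed 1.5-fold were recovered. Of 45555 simulated for abundance, 79 of 100 and 35 of 100 were. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9. Lower bounds for probes not well above background use, per channel after loess and Aquantile, the mean of the higher of the lowest signal among probes well above background and the probe's own signal.

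Gene names came from transcript accessions matched without versions to a RefSeq table of assembly GRCm38.p6, used for names only: 45 of 50 matched. No coordinates are given, because the array design names another build. The rule for named genes, fixed before the data were examined with the tests and most alternatives, was as follows. Among tested probes with 1 symbol and all 5 testosterone arrays on one side of the control mean, up to 12 per direction past the threshold were named, filled to 8 per direction with the smallest unadjusted p where fewer passed. Up to 4 members of each list were added, which gave Prdx2, and for IP against Sup the 8 highest and 8 lowest past the threshold. A gene that the rule takes for abundance is not reported here; its probe stays in the tests and counts. The genes the rule always names, among them m6A writers and Leydig cell genes, carry no name on the probes used here and are not analysed here. The 24 gene lists, cell type markers included, had 1 named gene between them and 0 had 5 tested genes, so no list was tested.

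The headers give 3 slides and 2 scans. Slide 1 held control replicates 1 to 4, slide 2 control replicate 5 and testosterone replicates 1 to 3, and slide 3, scanned separately, testosterone replicates 4 and 5. Comparisons were repeated with slide and scan as blocks, within slide 2 and within the first scan. Other alternatives were normexp background correction with an offset of 50 on the median signals (the files used here hold no mean signal), no filter, a filter on all 10 arrays, spike-in scaling, loess, Aquantile, quantile normalization, single channels, the authors' table, trended and robust eBayes, a threshold on the unadjusted p, the replicate number as a block and leaving out each replicate. No pair of arrays was identical, with a smallest root mean square difference of 0.327 on the log2 ratio.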

Results

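RNA was measured in testes of C57BL/6J mice, aged 3 months, whose mothers had been injected daily under the skin with testosterone at 2.5 mg/kg body weight, or with solvent alone, from day 14 to day 19 after mating. Each group held 5 samples, described as biological replicates in the labels, and each sample was hybridised to 1 array with 2 colours. The mothers were treated, and dam and litter were not among the sample details used here. All tests therefore take the 5 samples of a group as independent, which littermates would not be. On every array the immunoprecipitated RNA (IP) carried Cy5 and the RNA left in the supernatant (Sup) of the same sample carried Cy3. The labels do not name the antibody, so the IP/Sup ratio is given here as a fraction ratio and not as the level of a particular RNA modification. The arrays held 60706 mouse probes that were used. Of these, 50 carried a transcript accession, 45 of which matched a gene symbol, and the other 60656 have no gene name in the sources used here. The named genes below are therefore a small part of the transcripts measured, and the pathway and cell type lists fixed for this study could not be tested.

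Between 68.7% and 75.5% of probes were well above background in the Sup channel. In the IP channel the share was 71.8% to 76.4% on the 8 arrays of the first scan and 62.1% and 64.7% on the 2 arrays of the second scan, which were testosterone replicates 4 and 5. The median processed signal was lower in the testosterone group in both channels. In the IP channel it was 397 ± 7.96 (SD, n = 5) in controls and 312 ± 65.5 (SD, n = 5) after testosterone. The exact two-sided permutation p was 0.00794, the smallest value 5 against 5 arrays can give. This difference is not free of slide and scan. Testosterone replicates 4 and 5, on slide 3, were at 244 and 245. On slide 2, control replicate 5 was at 384 and testosterone replicates 1 to 3 at 323, 374 and 376. The median uncorrected spot intensity differed by less than the spread between arrays, at 63.1 ± 4.90 (SD, n = 5) and 58.3 ± 12.7 (SD, n = 5) in IP (exact two-sided permutation p = 0.492) and 90 ± 3.94 (SD, n = 5) and 88.4 ± 2.70 (SD, n = 5) in Sup (exact two-sided permutation p = 0.563). Testosterone replicates 4 and 5 lay apart from the other 8 arrays on the first principal component of RNA abundance, which held 45.0% of the variance, and control replicate 2 had the lowest median correlation of its IP/Sup ratios with the other arrays (r = 0.925 across probes, against 0.932 to 0.970 for the others).

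**Figure D1:**
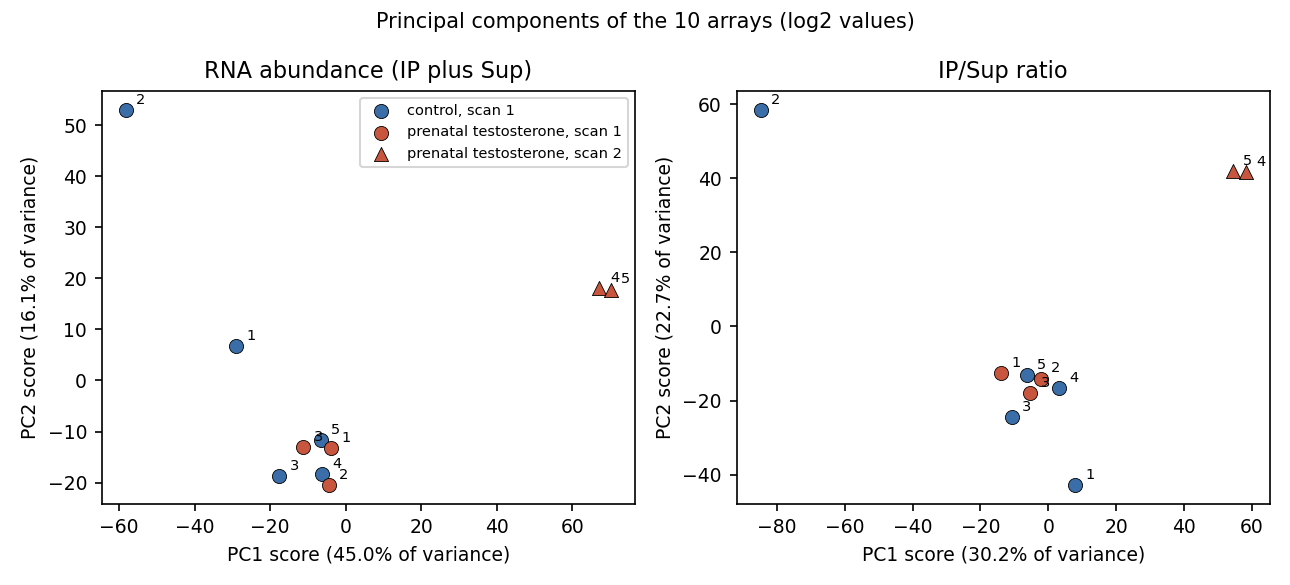
Scores of the 10 arrays on the first and second principal components of log2 RNA abundance (left) and of the log2 IP/Sup ratio (right), with axes giving the score and the percent of variance, colours the groups, shapes the scans and numbers the replicates. Testosterone replicates 4 and 5, at abundance scores of 67.2 and 70.2 on the first component, lie apart from the 8 arrays of the first scan, which lie between -58.2 and -3.87.

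The first question was which transcripts lay on the IP side and which on the Sup side in testis. Chgb, which encodes the secretory granule protein chromogranin B, had the highest ratio of the named genes, with a log2 IP/Sup ratio of 5.22 ± 0.066 (SE, n = 10), or 37.3-fold above the array median. Also on the IP side were Uhrf1bp1l at 2.87 ± 0.059 (SE), Rab5a, a small GTPase of early endosomes, at 2.64 ± 0.089 (SE), and Cep41, a centrosomal protein, at 2.18 ± 0.082 (SE). Taf1a, a subunit of the RNA polymerase I initiation factor SL1, had a log2 ratio of 1.45 ± 0.061 (SE). Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, was at 1.30 ± 0.063 (SE), Pex11a, a protein of peroxisome division, at 1.18 ± 0.067 (SE), and Ppara, a nuclear receptor for fatty acids, at 1.01 ± 0.077 (SE).

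On the Sup side, Rps4l, a ribosomal protein S4-like transcript, had the lowest log2 ratio of the named genes at -2.56 ± 0.072 (SE, n = 10). Acaa2, a thiolase of mitochondrial fatty acid oxidation, was at -2.29 ± 0.073 (SE). Prdx2, a peroxiredoxin and the only tested member of the oxidative stress list, was at -1.97 ± 0.099 (SE), and Gsta4, a glutathione S-transferase, at -1.94 ± 0.082 (SE). Gamt, which completes creatine synthesis, had a log2 ratio of -1.69 ± 0.073 (SE), Gsdmd, the pore-forming gasdermin D, -1.66 ± 0.091 (SE), Actb, cytoplasmic beta-actin, -1.49 ± 0.080 (SE), and Bambi, a decoy receptor of the TGF-beta family, -1.13 ± 0.085 (SE). Apoe, the lipid carrier apolipoprotein E, also passed, at -1.12 ± 0.097 (SE), beyond the 8 genes the naming rule takes.

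Of 41 tested probes with an accession, 17 passed limma's test at an adjusted p under 0.05 with at least a 2-fold ratio, 8 on the IP side and 9 on the Sup side. Over all 41424 tested probes, 8078 lay on the IP side and 8772 on the Sup side by the same threshold. Centred on the calibration spike-in RNA instead of the array median, the counts were 10296 and 6666, because the median mouse probe lay above the spike-ins. Background correction with normexp gave 4416 and 5915, and the log2 ratios of Taf1a at 0.96, Cpt1a at 0.93, Pex11a at 0.92 and Ppara at 0.50 were then under 2-fold. With spike-in centring Bambi at -0.87 and Apoe at -0.86 were under 2-fold, with loess Bambi at -0.97 and Apoe at -0.93, as was Ppara without control replicate 2, at 0.96, and without testosterone replicate 3 or 4, at 0.997 and 0.999. The 22 spike-in probes detected on all arrays, added in equal amount to both fractions, themselves ranged from -3.52 to 1.40 on the same scale, or from -1.56 without the lowest of them. Of these 22, 10 (45.5%) lay beyond 2-fold, against 40.7% of tested mouse probes, so a single ratio may hold a probe and dye part. Cpt1a, Pex11a, Ppara and all 9 genes on the Sup side lay within the full range of the spike-ins. Without the lowest spike-in, Actb, Bambi and Apoe on the Sup side still did. The SEs measure repeatability over arrays and do not cover such a part. Cav2, the membrane protein caveolin 2, was well above background in Sup on 10 of 10 arrays and in IP on 0, which puts it at least 1.56-fold higher in Sup, a bound open to dye bias since no dyes were swapped.

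**Figure D2:**
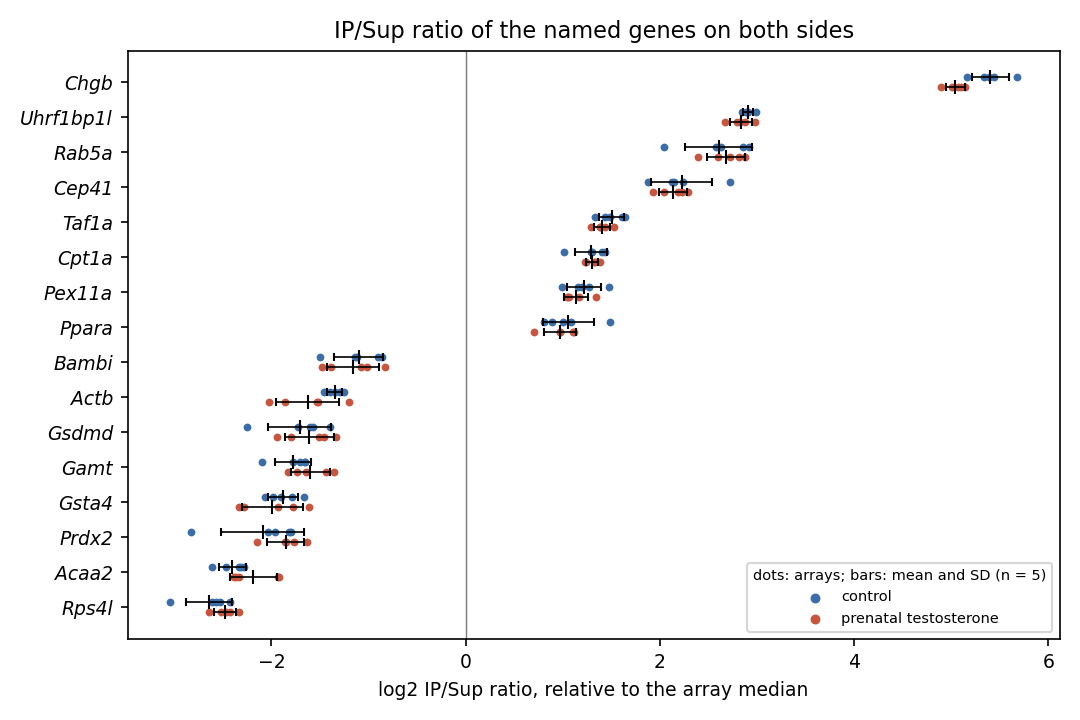
Log2 IP/Sup ratio relative to the array median (horizontal axis) for the 16 named genes, with 1 dot per array coloured by group, and bars for the mean and SD of each group (n = 5). The groups overlap for every gene but Chgb, whose testosterone arrays average 5.04 against 5.40 in controls.

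The second question was whether prenatal testosterone changed the IP/Sup ratio of transcripts in the adult testis. No gene passed. Chgb had the smallest unadjusted p of the named genes, with a log2 ratio of 5.40 ± 0.189 (SD, n = 5) in controls and 5.04 ± 0.096 (SD, n = 5) after testosterone, a difference of -0.36 ± 0.133 (SE) with a limma adjusted p of 0.794. All 5 testosterone arrays lay below the control mean, as the naming rule requires. The difference of Chgb was -0.30 without the second scan and -0.23 without the second scan and control replicate 2. H2-Q7 and H2-M2, genes of the major histocompatibility complex, had differences of -0.25 ± 0.163 (SE) and -0.17 ± 0.126 (SE), and Nup50, a nuclear pore protein, -0.22 ± 0.138 (SE). In the other direction, the olfactory receptor gene Olfr1307 had a difference of 0.31 ± 0.170 (SE), the small heat shock protein gene Hspb7 0.26 ± 0.139 (SE), Acaa2 0.22 ± 0.147 (SE) and Rps4l 0.16 ± 0.144 (SE). None of these 8 genes passed, and 0 of the 41 passed adjusted over the probes with an accession alone. Prdx2 had a difference of 0.24 ± 0.197 (SE), which was 0.05 without control replicate 2. Leaving out that array also gave 0.06 for Rps4l, -0.13 for H2-Q7 and -0.14 for Nup50, and leaving out testosterone replicate 5 gave 0.20 for Olfr1307. Without the 2 arrays of the second scan the differences were 0.11 for Olfr1307, 0.16 for Hspb7, -0.14 for H2-Q7 and -0.09 for H2-M2. Within the slide that held both groups they were -0.0083 for Olfr1307, 0.11 for Acaa2, -0.0030 for H2-Q7, -0.08 for H2-M2 and -0.09 for Nup50.

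Over all 41424 probes, 0 passed limma's test at an adjusted p under 0.05, the smallest adjusted p was 0.570, and 2505 had an unadjusted p under 0.05, 1085 higher and 1420 lower after testosterone. With limma, 0 passed without the 2 arrays of the second scan (1302 at an unadjusted p under 0.05), and with the scan as a block (1245). The second scan held only testosterone arrays, so with the scan as a block the difference comes from the first scan alone. These settings are therefore not separate checks. The slide that held both groups had 1 control and 3 testosterone arrays, and the difference with the slide as a block comes from these arrays alone. With that lone control, 0 probes with the slide as a block (682 at an unadjusted p under 0.05 with limma) and 0 within that slide (1981) say little about stability. The 22 spike-ins, which hold no mouse RNA, differed between the groups by a median absolute value of 0.09 on the same scale, from -1.36, or -0.50 without the lowest of them, to 0.38. Within the first scan the median absolute value was 0.15, from -0.64 to 0.30. In simulated data with 5 arrays per group, the test recovered 45 of 100 probes changed 2-fold in this ratio and 2 of 100 changed 1.5-fold, so changes of those sizes could be missed.

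The third question was whether the overall IP/Sup level differed, which centring on the median removes. The median log2 ratio of mouse probes minus that of the spike-ins was 0.21 ± 0.174 (SD, n = 5) in controls and 0.31 ± 0.167 (SD, n = 5) after testosterone. Dye normalization had already removed most of the mouse median, so this value rests mainly on the spike-ins. The difference of 0.11 was within the spread between arrays (exact two-sided permutation p = 0.365). Among the 8 arrays of the first scan it was -0.0040 (exact p = 1).

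The fourth question was whether RNA abundance, taken as the sum of both fractions, differed after testosterone. Both fractions were scaled to the same level first, so this sum weighs them alike and is not the total amount of a transcript. The largest named difference was in Hyal3, a hyaluronidase gene, at -0.46 ± 0.095 (SE) on the log2 scale. Hyal3 went from -1.06 ± 0.144 (SD, n = 5) in controls to -1.52 ± 0.115 (SD, n = 5) after testosterone. As the naming rule requires, all 5 of its testosterone arrays lay below the control mean. Its limma adjusted p was 0.233 over all probes, so it did not pass, and 0.0198 adjusted over the probes with an accession alone, a set given by the array and not fixed beforehand. On those probes alone it did not pass without the second scan (limma adjusted p = 0.0972) or with the scan as a block (0.0953), whose difference comes from the same arrays. Nor did it pass without the second scan and control replicate 2 (0.0834), or without control replicate 4 (0.0729), testosterone replicate 2 (0.0610) or testosterone replicate 5 (0.0531). Nor did any of those probes pass with normexp, with spike-in scaling, in Sup alone or with the replicate number as a block. Under these settings the lowest limma adjusted p ran from 0.0813 to 0.235. The slide that held both groups had only 1 control array, so a test there, or with the slide as a block, says little. The difference of Hyal3 was -0.41 without the second scan, -0.36 within the slide that held both groups and -0.12 with normexp. Hspb7, at -0.35 ± 0.114 (SE), Alkbh4, an AlkB homolog dioxygenase, at -0.33 ± 0.114 (SE), Spats1, a spermatogenesis-associated gene, at -0.30 ± 0.151 (SE), and Gsdmd, at -0.30 ± 0.110 (SE), did not pass. Nor did Mbp, myelin basic protein, at -0.29 ± 0.130 (SE), Taf1a at -0.23 ± 0.096 (SE) and Rab5a at -0.23 ± 0.082 (SE). Without the second scan the differences were -0.25 for Hspb7, -0.18 for Alkbh4, -0.15 for Rab5a, -0.14 for Gsdmd, -0.14 for Mbp, -0.13 for Taf1a and -0.09 for Spats1. Within the slide that held both groups these 7 lay between -0.21 for Alkbh4 and 0.09 for Spats1, and Mbp was at -0.0077 with normexp. Of 43 tested probes with an accession, 28 were lower and 15 higher, and 7 had an unadjusted p under 0.05, all lower. Without the second scan 23 were lower and 20 higher, and of those 7 only Hyal3 had an unadjusted p under 0.05. With spike-in scaling 40 were lower and 3 higher.

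Of 47646 probes, 3 passed limma's test at an adjusted p under 0.05, all lower after testosterone and all without a gene name. The probe ASMM10EP3A105527755 was well above background in both channels on all arrays and fell by 0.96 ± 0.089 (SE) on the log2 scale, or 1.94-fold, from 3.52 ± 0.110 (SD, n = 5) to 2.56 ± 0.120 (SD, n = 5), with an adjusted p of 0.0106. Its own IP/Sup ratio differed by -0.30 between the groups (limma adjusted p = 0.815). The probe ASMM10EP3A128339908 had a mean log2 abundance of -2.87 ± 0.077 (SD, n = 5) in controls and -3.60 ± 0.105 (SD, n = 5) after testosterone, with an adjusted p of 0.0355. After testosterone it was well above background on 0 of 5 arrays in IP and on 1 of 5 in Sup, so the IP change is only bounded, at least 1.04-fold lower. It did not pass with spike-in scaling (limma adjusted p = 0.318), quantile normalization (0.113), no filter (0.0693) or in IP alone (0.230). Nor did it with the replicate block (0.179) or with trended and robust eBayes (0.193). With 1 array left out, it passed only without testosterone replicate 5. The other probe was well above background on 4 of 5 control arrays and 0 of 5 testosterone arrays in either channel, at least 1.27-fold lower in IP and at least 1.04-fold lower in Sup, with an adjusted p of 0.0355. These probes were chosen after their values were seen. With normexp 3 probes passed, 2 higher and 1 lower, of which 1, ASMM10EP3A105527755, is among these, at -0.87. The 2 probes only bounded after testosterone, ASMM10EP3A128339908 and ASMM10EP3A113318660, did not pass with it, and their fitted differences, which are no bounds, were -0.0086 and -0.14 with normexp against -0.73 and -1.98 without.

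An unadjusted p under 0.05 was found for 7278 probes (15.3%), 2307 higher and 4971 lower, and of these 969 changed at least 1.5-fold, 511 higher and 458 lower. Without the second scan 1 probe passed and 3720 had an unadjusted p under 0.05. With the scan as a block 0 passed with limma (3687 at an unadjusted p under 0.05), with the slide as a block 2 passed, and within the slide that held both groups 2 passed, where the lone control is assumed to vary like the testosterone arrays. None of the 3 probes above was among those that passed under these 4 settings. The difference of ASMM10EP3A105527755 was -0.94 without the second scan (adjusted p = 0.0876) and -0.99 with the slide as a block (adjusted p = 1.00), and it did not pass with the replicate number as a block (-0.96, adjusted p = 0.179), with spike-in scaling (-1.09, adjusted p = 0.106) or in Sup alone (-0.72, adjusted p = 0.476). Its limma adjusted p over all alternatives ran from 0.000994 to 1.00. Leaving out control replicate 1, 3, 4 or 5 left 0 probes (5367, 6453, 7035 and 6836 at an unadjusted p under 0.05), and leaving out control replicate 2 or testosterone replicate 2 left 1, ASMM10EP3A105527755. The authors' value table, which holds the IP channel on a scale whose constant per array is of unknown origin, gave 471 probes, 23 higher and 448 lower. On that scale the median probe differed by -0.30 between the groups, against -0.04 on the scale used here and -0.14 with spike-in scaling.

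**Figure D3:**
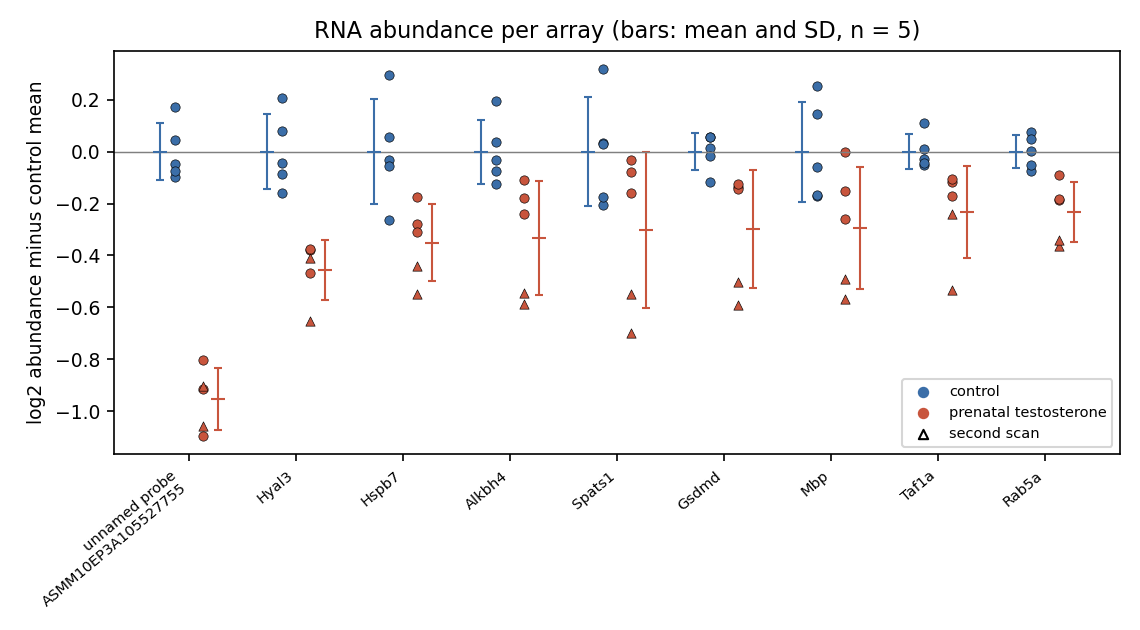
Log2 RNA abundance per array minus the control mean (vertical axis) for the unnamed probe ASMM10EP3A105527755 and 8 named genes, with dots for arrays, colours for groups, triangles for the second scan, and bars for the mean and SD (n = 5). The testosterone mean of the unnamed probe is 2.56 against 3.52 in controls with no overlap, whereas for 7 of the 8 named genes, all but Hyal3, the 2 arrays of the second scan lie lowest.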

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

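The tests of the second scan, of the spread of the IP/Sup ratio and of the splits for the unadjusted p were chosen after the results were seen. Those of the splits for the counts past the threshold were set before.

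In control replicate 2, the log2 IP/Sup ratio of Prdx2 was -2.83, against -2.03 to -1.80 on the other 4 control arrays, and that of Gamt was -2.09, against -1.78 to -1.65. Both lie farther from their group than a common rule for single outlying samples allows. Of 78 groups of 5 arrays tested, 2 did so, and chance gives about 1 in 20.

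Testosterone replicates 4 and 5 stood apart from replicates 1 to 3 in RNA abundance. The probes were divided by brightness into 3 parts of equal size. The brightest differed by a median absolute value of 0.23 on the log2 scale and the dimmest by 0.28. That ratio of 0.823 neither excludes nor needs lower signal as the cause. The signed medians, replicates 4 and 5 minus replicates 1 to 3, were -0.11 in the dimmest part, -0.03 in the middle and 0.09 in the brightest. The sign thus changed with brightness, which was not tested further. The spike-in probes, which hold no mouse RNA, differed by a median absolute value of 0.33. That was at the 95.6th percentile of 10000 brightness-matched sets of mouse probes (median 0.22). A separate slide and scan, or the labelling that went with them, would give this. The signed median of the spike-ins was 0.26, higher in replicates 4 and 5, with 7 of 22 lower. Abundance is scaled on mouse probes alone, so less mouse RNA against the spike-ins would also shift them this way, and the test does not decide. No biological explanation was tested, and a difference between the animals stays open beside the technical one.

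RNA abundance had 7278 probes at an unadjusted p under 0.05. Of the 126 possible splits of the arrays into 5 and 5, 100 were used, the real one and others drawn at random. Of these 100, 1 gave as many, the real one, with 6919 as the highest of the others drawn. Splits that kept testosterone replicates 4 and 5 on one side gave a median of 3692, and splits that parted them 802. Without that pair the share of such probes was 7.81%, yet leaving out testosterone replicates 2 and 5 gave 7.37%, so the pair was not the lowest of the 10 pairs. Leaving out 2 of replicates 1 to 3 gave 21.7% to 24.5%. The scan may therefore account for part of the excess. With the scan as a block, which the 5 control and 3 testosterone arrays of the first scan allow, 3687 probes were at an unadjusted p under 0.05. Prenatal testosterone stays open as an explanation for what remains, as does the slide, and neither was tested apart from other differences between the arrays. Slide 1 held only control arrays, slide 3 only testosterone arrays and slide 2 a single control, so a slide block says little.

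The IP/Sup ratio spread widely over probes. Its SD was 1.21 over the 22 spike-in probes and 1.43 over the tested mouse probes, a ratio of 0.845 (0.696 to 0.865 leaving out 1 spike-in at a time), and 10 of the 22 spike-ins (45.5%) lay beyond 2-fold against 40.7% of mouse probes (Fisher's exact p = 0.669). Probe and dye offsets may thus make up a large part of the ratio of a single probe. The spike-ins differed between the groups by a median absolute value of 0.09 over all arrays and 0.15 within the first scan, and 1 of the 22 by -1.36 and -0.64. A biological explanation, transcripts differing in how much of them was precipitated, was not tested.

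In the IP/Sup ratio, 0 probes passed in the real split (2505 at an unadjusted p under 0.05 with limma), so all 100 splits gave as many by construction and their count says nothing about chance. The highest of the others drawn was 1 probe. In RNA abundance 3 probes passed, 1 of the 100 splits gave as many, the real one, and the highest of the others drawn was 0. Other splits thus rarely gave such a count, but the arrays are not interchangeable, so chance is not excluded. Leaving out control replicate 1, 3, 4 or 5 left 0 probes. The real split is not free of the scan or of the slide, since slide 1 held only control arrays and slide 3 only testosterone arrays. With the scan as a block 0 passed with limma (3687 at an unadjusted p under 0.05), yet ASMM10EP3A105527755 differed by -0.94 ± 0.099 (SE) against -0.96 ± 0.089 (SE) without the block, with an adjusted p of 0.0693, so the lost call does not point to the scan.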

How the results depend on the processing

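The settings without the second scan, with the scan as a block, within slide 2, and without both the second scan and control 2, were added after seeing the data. The IP/Sup ratio had 0 probes past the threshold under every alternative but an unadjusted p under 0.05 with at least 1.5-fold (744), and the cause was the looser threshold. Aquantile and leaving out saturated probes move no value by construction. RNA abundance had 3 probes, against 969 with that threshold, 471 in the authors' table, 1 each with quantile normalization, no filter, the filter on all 10 arrays, the replicate block (ASMM10EP3A113318660) and without the second scan, and 0 each with the supernatant alone (limma, 4933 at an unadjusted p under 0.05), the scan as a block (3687) and without the second scan and control 2 (4317). Leaving out 1 replicate gave 0 to 4, and trended and robust eBayes gave 4, 1 higher and 3 lower. With normexp 3 passed, 2 higher and 1 lower, and with spike-in scaling 3, all lower, and 1 of the 3 under each was among those past the threshold in the comparison as reported. The cause was not tested. IP and Sup calls together were 10331 with normexp, 4416 on the IP side, against 16850 and 8078, and 16666 to 17051 without 1 replicate (7982 to 8215 on the IP side, 8612 to 8929 on the Sup side). The overall level difference was 0.0343 to 0.152 without 1 replicate and -0.0040 without the second scan.

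The replicate numbers gave no sign of pairing the samples. In a check of this, same-numbered arrays correlated at -0.030 to 0.043 in the ratio and -0.052 to 0.22 in abundance. These are not correlations of whole profiles, whose median per array was 0.925 to 0.970 in the ratio and 0.982 to 0.994 in abundance. Low values do not exclude a pairing. With the replicate block the overall level had p = 0.25 by exact sign flips, and the ratio 0 probes.

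Of named genes, Olfr1307 in the ratio was at -0.0083 with the slide as a block and within slide 2. Spats1 in abundance was at 0.088 with the slide as a block and within slide 2. Other values moved by over 1.5 times. With spike-in centring the ratio differences were -0.12 for Nup50, -0.14 for H2-Q7, -0.06 for H2-M2 and 0.27 for Rps4l, and with normexp 0.14 for Hspb7, 0.12 for Olfr1307 and 0.24 for Rps4l. In abundance, normexp gave -0.19 for Hspb7 and -0.15 for Spats1, and spike-in scaling -0.38 for Rab5a and -0.37 for Taf1a. No gene list alternative was run, nor the authors' table for the ratio, which holds 1 channel. Signal over background limits dim probes.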

Other observations

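Control spots for housekeeping genes were left out of the comparisons, and their ratios were not tested against 0. Of 4 such probes, 3 were well above background in both channels on all arrays, and the mean ratio of these 3 was below 0 in both groups, and over all arrays also when centred on the spike-ins, after loess and after normexp. Gapdh, a glycolytic enzyme, had a log2 IP/Sup ratio of -1.52 ± 0.231 (SD, n = 5) in controls and -1.44 ± 0.177 (SD, n = 5) after testosterone at its probe GAPDH_3, and -0.73 ± 0.049 and -0.79 ± 0.104 at GAPDH_5. Pgk1, another glycolytic enzyme, was at -0.95 ± 0.236 and -0.71 ± 0.152 at the probe PGK1_3, while the probe PGK1_5 was well above background on 0 of 10 arrays in either channel. Between the groups the 3 measured probes differed by -0.05 to 0.23 (exact two-sided permutation p of 0.111 to 0.540, adjusted 0.677 to 0.720 over 8 comparisons).

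Of 2064 tested probes whose names start with ASMM10SM, 8.19% lay on the IP side and 25.3% on the Sup side, against 20.1% and 21.2% of 33846 in the series ASMM10EP3A and 1090 and 1056 of 5458 probes in the series ASMM10EP3B. The ASMM10SM probes were also dimmer, with a median log2 abundance in controls of -1.13, against -0.05 for ASMM10EP3A and -0.25 for ASMM10EP3B. A smaller share of them was tested for the ratio, 2064 of 4087 against 33846 of 48057 for ASMM10EP3A. What distinguishes the series is not stated in the sources used here. No test of the difference in IP and Sup calls was run, and brightness was not set apart from it.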
